A study of Mus musculus with 6 samples.

How the data were processed

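Gene expression in the jejunum of 6 irradiated mice was measured on 6 arrays with 1 colour channel and probes of 60 bases, with 3 mice given VND3207 and 3 given the vehicle. Groups, dose and times were taken from the labels before the data were examined, as were the tests, the gene lists and the rule for named genes. Per the file headers and the submitters' processing notes, the scanner files were made with Agilent Feature Extraction 10.7.1.1. The deposited intensity values used here are its processed signal, which per the file headers is the Cy3 signal of each spot after detrending within the array and subtraction of the background, with no scaling between arrays. The deposited value table holds log2 values whose 6 columns share the same median of 6.05 and 75th percentile of 9.41, as after quantile normalization. How that table was made is not stated, and its columns correlated across probes with the log2 processed signal of the same array at an r from 0.997 to 1.000. All value columns were matched to a sample, leaving 0 without one.

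Spots marked as outliers by the scanner software and control spots were left out, and the spots of a probe were averaged. Processed signals were turned to log2 and the 75th percentile of the 59305 non-control spots of each array was subtracted. Of 55681 non-control probes, 36088 were kept for being well above background on at least 3 of the 6 arrays whatever their group. Probes were named by RefSeq accession (26582 probes), current symbol (2549), older symbol (481) or the file's own gene name (1192), and 24877 had no name. The annotation supplied names only, and probe positions are those of the mm9 build given in the files. Each gene was represented by its probe with the highest mean over all arrays, a choice that mattered for 4519 genes with more than 1 kept probe. Probes without a gene name were tested with the others and counted apart, giving 147 higher and 3315 lower of 13044.

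Differences were tested with limma 3.58.1 (lmFit and eBayes, 2-sided, group as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment over the 30589 features tested and a threshold of 0.05. The errors given with ± are moderated standard errors of limma. Of 38 gene lists fixed beforehand, 37 had the 5 measured members needed. They were tested with camera at a preset correlation of 0.01, with camera at a correlation estimated for each list, and with fry, each adjusted over the lists. The score of a list in a mouse is the median over its members of the log2 signal minus the gene's mean over the 6 arrays. For a gene with no array of a group well above background, the fold is a lower bound. It was taken against the mean over that group's arrays of the gene's signal or, where this is higher, of the lowest probe signal called well above background on the array.

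Named genes were the 12 largest increases and 12 largest decreases among genes past the threshold whose groups did not overlap, up to 4 members of each list, and Cdkn1a, Mdm2, Bbc3, Prkdc and Trp53. The largest changes among genes brighter than the 75th percentile were named after their values were seen.

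The alternatives chosen beforehand were quantile normalization, normexp background correction with an offset of 50, the deposited value table, other filters on dim probes, the mean of a gene's probes, probes not collapsed to genes, other variance models and array weights, the replicate number as a block, each array left out in turn, other thresholds and other set tests. Tests of brighter genes only and a correction of each array for spot position, brightness and probe GC content, made with smooth trends in mgcv 1.9.3, were added after the data were seen. The correction can also remove part of a true difference that follows those trends. Slide and scan could not be fitted as a block because each holds 1 group only.

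On simulated data with 50 changed genes at each size, the pipeline recovered 0% at 1.25-fold, 2% at 1.5-fold, 30% at 2-fold and 72% at 4-fold, and called 2 of 17325 unchanged named genes. In the real data 143 named genes were called higher and 1616 lower. With fewer changed genes, the Benjamini-Hochberg adjustment asks for a smaller unadjusted p. The simulated shares and false calls therefore do not give the power or error rate of the real comparison. A simulated list shifted by 0.3 had a camera adjusted p of 6.15e-10 and an unshifted list 0.116. The genes of both lists were drawn independently, whereas the estimated correlation of the cholesterol synthesis list was 0.426. A further simulation added a row trend to dim spots of 1 group, of a form that the correction fits. It used 2-fold changes and the same SD for all probes. There the correction brought the unchanged probes called lower from 6839 to 1 and the share of changed probes recovered from 90.5% to 98.5%. This outcome does not show how the correction acts on other trends or on a difference between slides. No spot was saturated, and values below the background of an array limit what can be read for dim genes. Data were read with the data.table package (version 1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.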

Results

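Gene expression was measured in the jejunum of 6 male C57BL/6J mice with 1-colour oligonucleotide arrays. VND3207, a compound the labels give only by this code name, was administered into the stomach at 100 mg/kg to 3 mice, and 3 control mice received the vehicle. All mice were given 9 Gy of radiation 0.5 h later, and the jejunum was taken 6 h after the radiation. The comparison therefore asks what VND3207, given before radiation, changed in the irradiated intestine. Unirradiated tissue was not analysed here, so the response to radiation itself has no measure in these data. Each array carried 62976 spots, of which 66.7% to 70.0% of the non-control spots were well above background on the vehicle arrays and 58.8% to 61.4% on the VND3207 arrays. After filtering, 17545 named genes and 13044 probes without a gene name were tested. All 3 vehicle arrays came from slide 1 and scan 1 and all 3 VND3207 arrays from slide 2 and scan 2, so batch and group cannot be told apart in any comparison below. The number of arrays limits the precision of every value.

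The list of cholesterol synthesis genes had a median log2 difference of 0.31 in the mice given VND3207, with 2 of 20 members past the threshold. It passed with camera at a preset correlation (adjusted p = 7.78e-06) and not with an estimated correlation (adjusted p = 0.822) or fry (adjusted p = 0.218). Cdkn1a and Mdm2, classical p53 targets of the damage response, differed by 0.07 and 0.04 and did not pass the test. Among well measured transcripts, the chaperone gene Hspa8 fell by 1.00 on the log2 scale (SE 0.11) on its brightest probe, the T cell co-receptor gene Cd4 by 1.18 (SE 0.15) and the Paneth cell defensin gene Defa26 by 0.94 (SE 0.13), with n = 3 and 3. Ly6a, the gene of the surface protein Sca-1, rose by 0.76 (SE 0.14). In all, 143 named genes were higher and 1616 lower with VND3207 (limma, Benjamini-Hochberg adjusted p under 0.05), so that 8.13% of the calls were higher. Of the genes called lower, 441 were not well above background on any VND3207 array, and 1365 were dimmer than the 75th percentile of the arrays. The values of the groups did not overlap for 28.8% of the named genes, where chance gives 10%. Quantile normalization gave 371 genes higher and 986 lower, or 27.3% of the calls higher. A correction of each array for trends with spot position, brightness and probe GC content, chosen after seeing the data, gave 634 higher and 752 lower, or 45.7% of the calls higher.

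Cholesterol synthesis genes were higher with VND3207 in 18 of 20 measured members, with a median log2 difference of 0.31. Lss, which encodes lanosterol synthase, rose by 0.66 ± 0.15 (SE, n = 3 and 3, limma adjusted p = 0.0335), and Fdps, which encodes farnesyl diphosphate synthase, rose by 0.57 ± 0.13 (adjusted p = 0.0336). The Lss probe lies on chromosome 10 at 76015992 to 76016051 and the Fdps probe on chromosome 3 at 88897549 to 88897608, on the mm9 build of the file headers. The other 18 members did not pass, among them Sqle, the squalene epoxidase gene, at 0.50 ± 0.14 (adjusted p = 0.0597) and Cyp51 at 0.42 ± 0.13 (adjusted p = 0.0878). The same 2 members were counted when p was adjusted over the list alone. In 9 of the 20 members all VND3207 arrays were above all vehicle arrays, 45% against 11.2% of all named genes, where chance gives 5%. The list's score was 0.29 and 0.28 in VND3207 replicates 1 and 3 but -0.05 in replicate 2, against -0.22 to -0.13 in the vehicle mice. The list as a whole was higher than the other features tested, among them 13044 probes without a gene name (camera with a preset correlation of 0.01, adjusted p = 7.78e-06). After the correction for spot position, brightness and GC content its median was 0.28 (adjusted p = 0.00328, or 0.948 with an estimated correlation). The call was lost with an estimated correlation (adjusted p = 0.822), the estimate for this list being 0.426. Without any 1 array other than VND3207 replicate 2, neither Lss nor Fdps passed, with an adjusted p of up to 0.111 and 0.108. With 3 mice per group, an exact two-sided permutation of the list's score cannot give a p below 0.10.

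**Figure D1:**
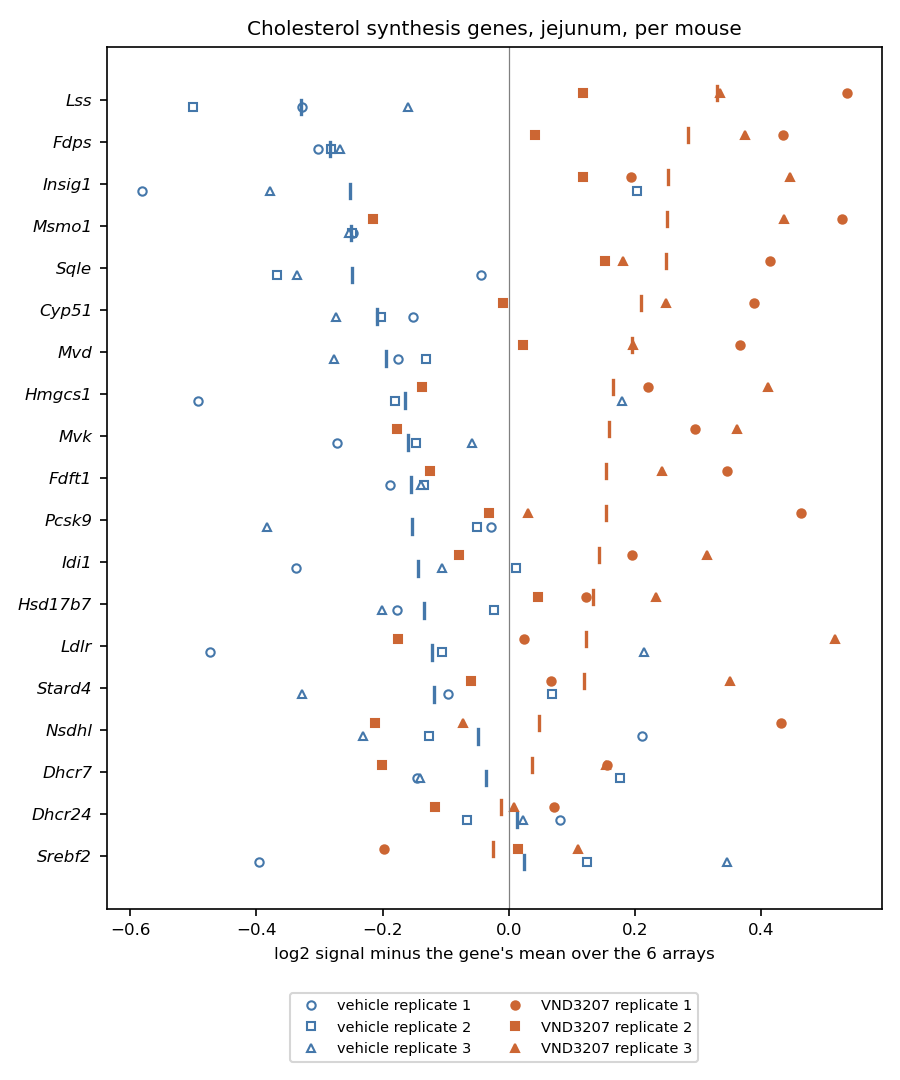
Log2 signal of cholesterol synthesis genes in each mouse, minus the gene's mean over the 6 arrays, with 1 of the 20 measured genes not drawn, with vehicle mice as open blue and VND3207 mice as filled orange symbols and vertical bars at the group means. The group means are farthest apart for Lss, at 0.66, and Fdps, at 0.57, with VND3207 to the right of vehicle.

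Among genes of the DNA damage response, 3 of the 32 p53 targets rose and 0 fell. These were Pmaip1, which encodes the pro-apoptotic protein Noxa, at 0.61 ± 0.15 (adjusted p = 0.0376), Ei24 at 0.44 ± 0.09 (adjusted p = 0.023) and Btg2, an antiproliferative gene, at 0.41 ± 0.10 (adjusted p = 0.0342), while Trp53inp1 was at 0.36 ± 0.11 (adjusted p = 0.079). After the correction for spot position, brightness and GC content none of the 3 passed, with Pmaip1 at 0.56 (adjusted p = 0.0721), Ei24 at 0.21 (adjusted p = 0.189) and Btg2 at 0.26 (adjusted p = 0.115), while Ppm1d, at 0.34 before it (adjusted p = 0.0799), passed at 0.48 (adjusted p = 0.0324). With p adjusted over the list alone, 0 passed. Cdkn1a, the gene of the cell cycle inhibitor p21, was at 0.07 ± 0.10 (adjusted p = 0.706), Mdm2 at 0.04 ± 0.12 (adjusted p = 0.858) and Bbc3, the gene of the pro-apoptotic protein Puma, at 0.19 ± 0.11 (adjusted p = 0.33). Prkdc, the gene of the catalytic subunit of DNA-dependent protein kinase, was at 0.09 ± 0.12 (adjusted p = 0.707) and Trp53 itself at -0.44 ± 0.14 (adjusted p = 0.0843), or 0.04 after the correction. With the correction Cdkn1a was at 0.26, Mdm2 at 0.18, Bbc3 at 0.29 and Prkdc at 0.27, and none of them passed (limma adjusted p from 0.114 to 0.322). The p53 list had a median of 0.07 and passed with camera (adjusted p = 0.000889), but not with an estimated correlation (adjusted p = 0.732).

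The mitosis list had 17 of 21 members above 0. Of these, 0 passed by themselves or when adjusted over the list alone, with Bub1b, a spindle checkpoint kinase gene, at 0.35 ± 0.09 (adjusted p = 0.0571). The list median was 0.13 (camera adjusted p = 0.0136, with an estimated correlation adjusted p = 0.822). DNA replication genes had 14 of 24 members above 0, of which 0 passed either way, and a median of 0.05 (camera adjusted p = 0.0315, with an estimated correlation adjusted p = 0.822), Mcm2 being at 0.39 ± 0.15 (adjusted p = 0.151). In the list of end joining and damage signalling, 17 of 21 members were above 0, with a median of 0.11 (camera adjusted p = 0.0323, with an estimated correlation adjusted p = 0.736). The single member of that list past the threshold, also when adjusted over the list alone, was the checkpoint kinase gene Chek1, which fell by 1.03 on the log2 scale (SE 0.14, adjusted p = 0.00509), against the direction of its list. Homologous recombination had 1 of 20 members lower, the meiotic recombinase gene Dmc1, which was not well above background on any VND3207 array and was at least 3.29-fold lower (adjusted p = 0.0137). The median of that list was -0.07 (camera adjusted p = 0.389). Among 21 apoptosis regulators outside the p53 list, Hrk was likewise at least 3.33-fold lower (adjusted p = 0.00314) and the other 20 did not pass, with a list median of 0.03 (camera adjusted p = 0.166). After the correction for spot position, brightness and GC content, none of the lists for p53 targets (median 0.10, adjusted p = 0.36), mitosis (median 0.03, adjusted p = 0.657), DNA replication (median 0.09, adjusted p = 0.764) and end joining (median -0.03, adjusted p = 0.841) passed, and Chek1 was at -0.25 (adjusted p = 0.216). Dmc1 and Hrk stayed lower, and 3 members of the lists of this paragraph that had not passed before were higher, namely the mitotic kinase gene Ttk at 1.05 (adjusted p = 0.0283), the recombination gene Eme1 at 0.86 (adjusted p = 0.00937) and Tnfrsf1a, a tumour necrosis factor receptor gene of the apoptosis list, at 0.46 (adjusted p = 0.0297). Before the correction these 3 were at 0.15, 0.29 and 0.31.

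In the epithelium, 5 of 25 absorptive enterocyte genes fell and 0 rose, also when adjusted over the list alone. Fabp1 was at -0.82 ± 0.13 (adjusted p = 0.00917), Anpep, the brush border aminopeptidase gene, at -0.77 ± 0.13 (adjusted p = 0.0108) and Fabp2 at -0.58 ± 0.12 (adjusted p = 0.0222). Lct at -0.39 (adjusted p = 0.048) and Vil1 at -0.36 (adjusted p = 0.0473) also fell. The list had a median of -0.23 (camera adjusted p = 0.389). Of 12 Paneth cell genes, 3 fell, namely Defa26 at -0.94 ± 0.13 (adjusted p = 0.00625), the lysozyme gene Lyz1 at -0.65 ± 0.09 (adjusted p = 0.0058) and Itln1 at -0.41 ± 0.10 (adjusted p = 0.0395), with a list median of -0.13 (camera adjusted p = 0.472). Quantile normalization turned the enterocyte median to 0.05 and the Paneth median to 0.13. It left Fabp1 at -0.39 (adjusted p = 0.0653), Anpep at -0.35 (adjusted p = 0.0681), Fabp2 at -0.13 (adjusted p = 0.395), Lyz1 at -0.29 (adjusted p = 0.123) and Itln1 at 0.01 (adjusted p = 0.963), while Defa26 passed at -0.69 (adjusted p = 0.0431). After the correction Fabp1, Fabp2 and Defa26 passed, as did the defensin gene Defa23 at -0.81 (adjusted p = 0.0191). The enterocyte and Paneth medians were then -0.03 and -0.03 (camera adjusted p = 0.509 and 0.374). Anpep was then at -0.38 (adjusted p = 0.0769), Lct at -0.39 (adjusted p = 0.0513), Vil1 at -0.03 (adjusted p = 0.872), Lyz1 at -0.43 (adjusted p = 0.0579) and Itln1 at -0.17 (adjusted p = 0.443). The 2 brightest control transcripts of the arrays, with vehicle means of 7.51 and 9.07, were at -0.40 and -0.32. The next brightest, with a vehicle mean of 6.66, was at 0.11. The median brightness was 6.36 for the enterocyte list and 7.58 for the Paneth list. None of 17 goblet cell genes passed, with Creb3l1 at -0.41 ± 0.11 (adjusted p = 0.0523) and Tff3 at -0.33 ± 0.10 (adjusted p = 0.0691), and a list median of 0.08 (camera adjusted p = 0.42). After the correction 3 of them were lower, Creb3l1 at -0.63 (adjusted p = 0.0201), Tff3 at -0.50 (adjusted p = 0.0357) and Zg16 at -0.52 (adjusted p = 0.0262). No member passed among 20 enteroendocrine genes (median 0.02, camera adjusted p = 0.196) or 18 crypt base stem cell genes (median 0.01, camera adjusted p = 0.152). Of 14 tuft cell genes, 1 fell, the transcription factor gene Pou2f3 at -0.87 ± 0.12 (adjusted p = 0.00549), with a list median of -0.06 (camera adjusted p = 0.957). After the correction for spot position, brightness and GC content Pou2f3 was at 0.09.

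Epithelial regeneration and YAP target genes were higher in 11 of 14 members, with a median of 0.19 (camera adjusted p = 0.0136, with an estimated correlation adjusted p = 0.822). Ly6a rose by 0.76 ± 0.14 (adjusted p = 0.0144) and its neighbour in the gene family, Ly6c1, by 0.54 ± 0.13 (adjusted p = 0.0364). These were also the 2 members called when adjusted over the list alone. Both passed after the correction (adjusted p = 0.0396 and 0.0383), whereas the list did not (median 0.13, adjusted p = 0.361). With quantile normalization Ly6c1 was at 0.57 (adjusted p = 0.0645), and without VND3207 replicate 1 Ly6a was at 0.71 (adjusted p = 0.0541). Both proteins are also found on endothelial and immune cells. Of 14 epithelial antimicrobial genes, Sprr1a and Reg3b fell, at -0.88 ± 0.17 (adjusted p = 0.0163) and -0.44 ± 0.11 (adjusted p = 0.0415), and 3 were called lower when adjusted over the list alone. The list median was 0.08 (camera adjusted p = 0.606). Reg3b was at 0.01 after quantile normalization, and after the correction Sprr1a was at -0.79 (adjusted p = 0.0525) and Reg3b at -0.36 (adjusted p = 0.108).

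Among genes of stress and metabolism, Hspa8, which encodes a constitutive chaperone, fell by 1.00 on the log2 scale (SE 0.11, adjusted p = 0.00314) on the reported probe, 1 of 3 whose values reached up to -0.14, while the other 13 measured heat shock genes did not pass. Hspa1a was at -0.93 ± 0.27 (adjusted p = 0.0647) and the list median at -0.20 (camera adjusted p = 0.196). After the correction Hspa8 was lower at -0.73 (adjusted p = 0.0101) and so was Hspa4l at -0.44 (adjusted p = 0.0366). Aldh3a1, an aldehyde dehydrogenase gene, was the 1 of 21 NRF2 and antioxidant genes that changed, and it fell by 1.00 on the log2 scale (SE 0.14, adjusted p = 0.00554), although its other probe was at 0.18, with a list median of -0.07 (camera adjusted p = 0.606). Ribosomal protein genes had 5 of 21 members lower, such as Rps3 at -0.58 ± 0.10 (adjusted p = 0.0117) and Rpl23 at -0.53 ± 0.10 (adjusted p = 0.0153). The list median of -0.17 (camera adjusted p = 0.152) turned to 0.13 with quantile normalization, and after the correction Rps3 was at -0.36 (adjusted p = 0.0671) and Rpl23 at -0.26 (adjusted p = 0.12). Oxidative phosphorylation had 1 of 22 lower, the ATP synthase gene Atp5b at -0.52 ± 0.10 (adjusted p = 0.0201), and the same median of -0.17 (camera adjusted p = 0.148), or 0.01 after the correction for spot position, brightness and GC content, which left Atp5b at -0.06 (adjusted p = 0.777). Of 15 immediate early genes, the phosphatase gene Dusp1 rose by 0.51 ± 0.11 (adjusted p = 0.0237), with 0.43 after the correction (adjusted p = 0.0827), where Junb was higher at 0.63 (adjusted p = 0.03), and the list median was -0.02 (camera adjusted p = 0.148). In the glucocorticoid response list 1 of 14 members fell, Cyp11b1, an enzyme gene of corticosteroid synthesis, at least 3.16-fold (adjusted p = 0.0162). The list median was 0.24 (camera adjusted p = 0.0536), with Zbtb16 at 0.81 ± 0.26 (adjusted p = 0.0961). After the correction Cyp11b1 stayed lower and Pnmt, an enzyme gene of adrenaline synthesis, was higher at 0.97 (adjusted p = 0.0175), from 0.23 before it. No member passed in the lists of the unfolded protein response (18 genes, median 0.00, camera adjusted p = 0.166), fatty acid oxidation and PPAR targets (19 genes, median -0.04, camera adjusted p = 0.606), xenobiotic metabolism (22 genes, median -0.20, camera adjusted p = 0.957) and the circadian clock (17 genes, median -0.02, camera adjusted p = 0.2).

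Among immune cell lists, T and NK cell genes had 16 of 19 members above 0 and a median of 0.14 (camera adjusted p = 0.0388, with an estimated correlation adjusted p = 0.822). After the correction the list had a larger median of 0.27 and an adjusted p of 0.36, and without VND3207 replicate 3 its median was -0.04 (adjusted p = 0.28). The 2 members past the threshold, also when adjusted over the list alone, fell against that direction. These were Cd4 at -1.18 ± 0.15 (adjusted p = 0.00492) and Cd247, a T cell receptor signalling chain, at -0.66 ± 0.12 (adjusted p = 0.0125). After the correction Cd4 passed and Cd247 was at -0.20 (adjusted p = 0.382). Cd8b1 at 1.27 (adjusted p = 0.0464) and Itgae at 0.95 (adjusted p = 0.0218) were then higher, in the direction of the list, from 0.97 and 0.15 before it. The interferon response list had 21 of 24 members above 0, of which 0 passed either way, with Mx1 at 0.32 ± 0.12 (adjusted p = 0.131). The list median was 0.20 (camera adjusted p = 0.0267, with an estimated correlation adjusted p = 0.822). That median was -0.21 without vehicle replicate 3, and after the correction it was 0.21 and did not pass (adjusted p = 0.36). Inflammatory cytokines and NF-kB targets had no member of 15 past the threshold and a median of 0.16 (camera adjusted p = 0.166). After the correction the adhesion gene Icam1 was higher at 1.24 (adjusted p = 0.0223) and the cyclooxygenase gene Ptgs2 at 0.70 (adjusted p = 0.038), from 0.56 and 0.35 before it. Genes of MHC class II presentation had H2-Ob lower at -1.65 ± 0.21 (adjusted p = 0.00441), with a list median of 0.23 over 9 genes (camera adjusted p = 0.245). Those of macrophages, dendritic cells and neutrophils had the integrin gene Itgam lower at -0.75 ± 0.18 (adjusted p = 0.0399), although another of its probes was at 0.55, with a median of 0.17 over 16 genes (camera adjusted p = 0.136). B and plasma cell genes had Cr2 and Fcer2a lower at -0.84 ± 0.18 and -0.63 ± 0.13 (adjusted p = 0.0227 and 0.0213) and a median of 0.00 over 11 genes (camera adjusted p = 0.901). Of the 4 mast cell genes measured, too few for a list test, Tpsb2 fell by 0.56 (SE 0.12, adjusted p = 0.0231). After the correction Cr2 was at -0.14, Fcer2a at 0.16 and the B cell gene Cd22 higher at 0.60 (adjusted p = 0.0281), from 0.03 before it, and Tpsb2, at 0.00, no longer passed (adjusted p = 0.999). Nor did H2-Ob, at -0.77 (adjusted p = 0.0605) and with its other probe at -0.05 before correction, or Itgam, at -0.61 (adjusted p = 0.0795).

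Smooth muscle genes had a median of -0.64 with VND3207 (15 genes, 0 past the threshold, camera adjusted p = 0.616), with Des, the desmin gene, at -1.01 ± 0.68 (adjusted p = 0.406). VND3207 replicate 3 had a score of -1.73 for that list, against 0.17 to 0.57 in the other mice, and without it the median was 0.13 (camera adjusted p = 0.0333). Enteric neuron and glia genes were lowest in the same mouse, at -0.96. In that list 3 of 13 genes fell, namely Gfap, the astrocyte and enteric glia filament gene, at -1.34 ± 0.24 (adjusted p = 0.0132), the synaptic gene Snap25 at -0.80 ± 0.17 (adjusted p = 0.0231) and Sox10 at -0.51 ± 0.11 (adjusted p = 0.023), with a list median of -0.23 (camera adjusted p = 0.564). After the correction Snap25 passed, and Gfap was at -0.56 (adjusted p = 0.206) and Sox10 at -0.16 (adjusted p = 0.393). Adipose tissue genes spanned scores from -1.99 to 2.81 between mice (median 1.19, 10 genes, camera adjusted p = 0.148), with Adipoq, the adiponectin gene, at 1.90 ± 1.93 (adjusted p = 0.602). Pancreatic acinar genes were below 0 in all 11 measured members, of which 3 passed, with a median of -0.49 (camera adjusted p = 0.148). After the correction Cela1, Pnliprp1, Clps and Ctrl were above 0, at 0.28, 0.23, 0.08 and 0.03, and the median was -0.27 (camera adjusted p = 0.39). The digestive enzyme genes Cpa1 and Cela3b were not well above background with VND3207 and at least 6.86-fold and 3.97-fold lower (adjusted p = 0.0444 and 0.0186), and Cel fell by 1.00 on the log2 scale (SE 0.24, adjusted p = 0.0358). None of these 3 passed after the correction, with Cpa1 at least 3.67-fold (adjusted p = 0.134) and Cela3b at least 2.03-fold lower (adjusted p = 0.127) and Cel at -0.64 (adjusted p = 0.122), and without vehicle replicate 2 the bound for Cpa1 was 4.08-fold. Fibroblast and matrix genes had Pdgfra and Pdgfrb, receptors for platelet-derived growth factor, higher at 0.58 ± 0.15 and 0.41 ± 0.10 (adjusted p = 0.0497 and 0.0393), and at 0.37 and 0.25 after the correction (adjusted p = 0.16 and 0.148). Col15a1 was lower at -0.64 ± 0.16 (adjusted p = 0.0449), or 0.26 after the correction, with a list median of 0.08 over 14 genes (camera adjusted p = 0.0592). Endothelial genes had Kdr, a receptor for vascular endothelial growth factor, and Pecam1 lower at -0.60 ± 0.12 and -0.56 ± 0.10 (adjusted p = 0.0213 and 0.013), although the other Kdr probe was at 0.61, with a list median of 0.15 over 14 genes (camera adjusted p = 0.0777). After the correction Kdr stayed lower at -0.53 (adjusted p = 0.0325), Pecam1 was at -0.15 (adjusted p = 0.381) and Tek was higher at 0.71 (adjusted p = 0.0404), from 0.001 before it.

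**Figure D2:**
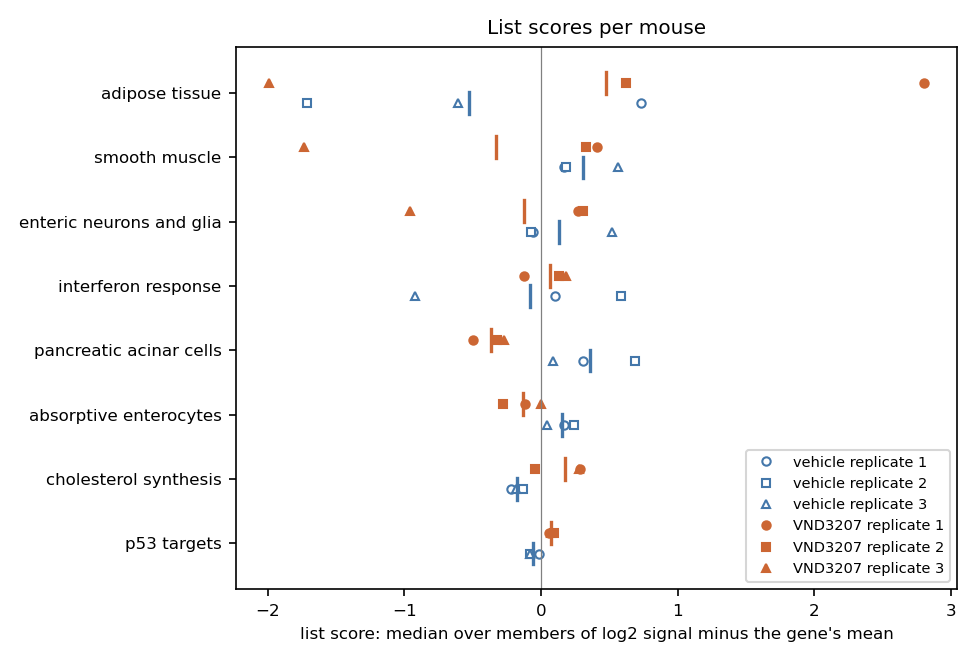
Score of 8 gene lists in each mouse, as the median over members of the log2 signal minus the gene's mean over the 6 arrays, with vehicle mice as open blue and VND3207 mice as filled orange symbols and vertical bars at the group means. VND3207 replicate 3 stands apart for smooth muscle at -1.73 and for enteric neurons and glia at -0.96. Cholesterol synthesis scores of the VND3207 mice lie above those of the vehicle mice, but VND3207 replicate 2, at -0.05, is near the highest vehicle mouse, at -0.13.

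Of the 37 lists tested, 8 were higher and 0 lower with camera at the preset correlation, against 12 and 0 at an unadjusted p under 0.05. With an estimated correlation there were 0 and 0 (unadjusted 2 and 0), and 0 and 0 with fry (unadjusted 3 and 4), which asks whether a list's genes move on balance in 1 direction. Adjusted over the list alone, Itgam and Atp5b were no longer counted and 4 pancreatic acinar genes were lower, and where nothing was said of it the count was that over all genes. Of those 8 calls, cholesterol synthesis remained after the correction for spot position, brightness and GC content, though not with an estimated correlation (adjusted p = 0.948), and the other 7 did not. The medians of p53 targets, DNA replication, interferon response and T and NK cells were no smaller after the correction than before. Camera compares a list with the other features tested, which include 13044 probes without a gene name. The median log2 difference of those probes was -0.24, against -0.01 for named genes, which favours upward calls of lists. The direction given by camera was upward for homologous recombination, NRF2 genes, fatty acid oxidation, immediate early genes, the circadian clock and B cells although their medians were below 0. It was also upward for apoptosis regulators, whose mean was -0.04. The means were above 0, at 0.04 and 0.06, for immediate early genes and the circadian clock. Whether the probes without a gene name account for these directions was not tested.

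**Figure D3:**
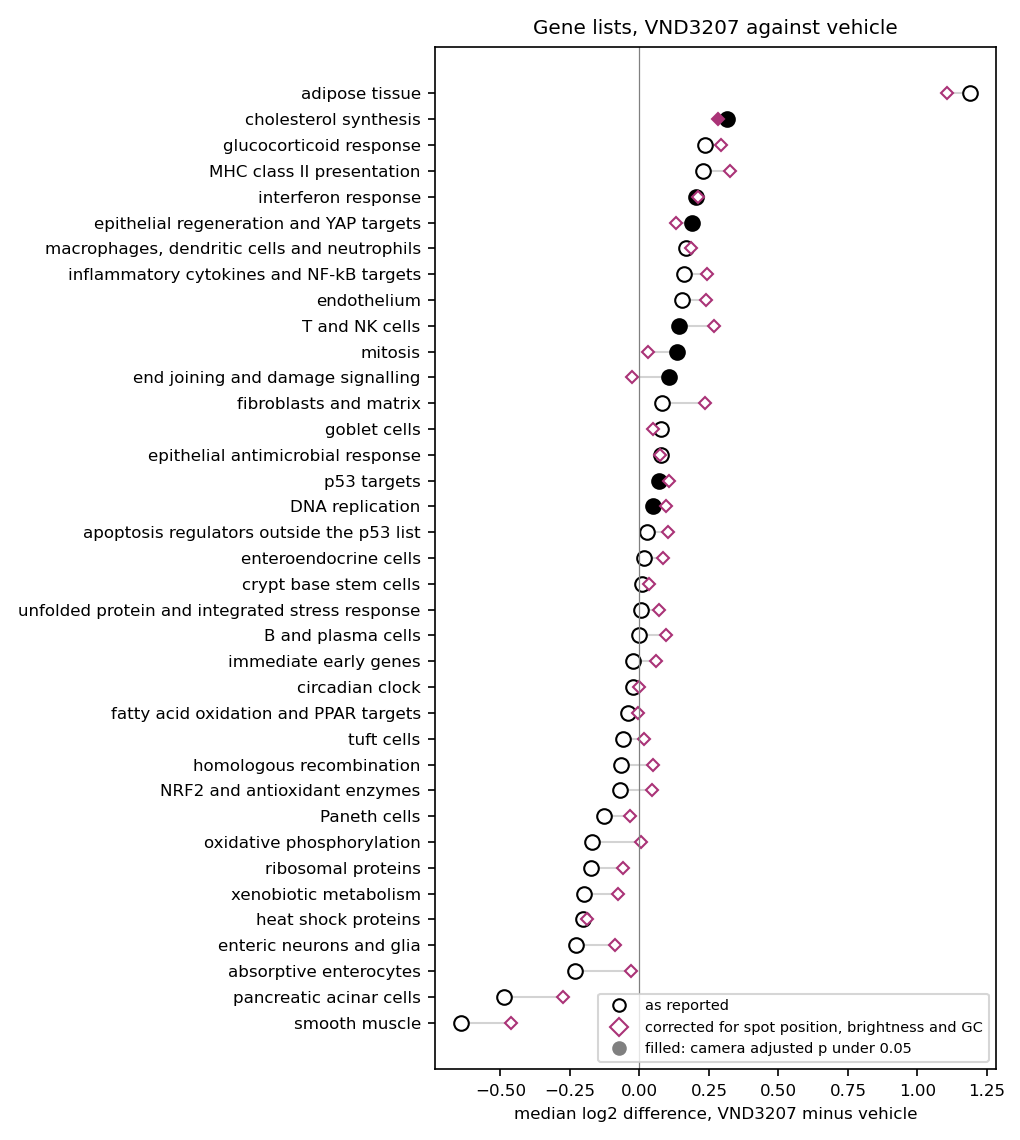
Median log2 difference, VND3207 minus vehicle, of the 37 gene lists tested, as reported (circles) and after the correction for spot position, brightness and probe GC content (diamonds), filled where camera at the preset correlation gave an adjusted p under 0.05. Of the 8 filled circles, only that of cholesterol synthesis, at 0.31, has a filled diamond, at 0.28.

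The largest increases among single genes were mostly of dim probes. Cylc1, a sperm head cytoskeleton gene on the X chromosome, was not well above background in any vehicle mouse and was at least 34.5-fold higher with VND3207 (adjusted p = 0.00414). Its SD between VND3207 mice was 1.32 on the log2 scale. The bound was 23.8-fold, 30.2-fold and 57.4-fold without VND3207 replicates 1, 2 and 3, and 28.3-fold after the correction. The olfactory receptor gene Olfr424 and the G protein-coupled receptor gene Mas1 were likewise at least 3.48-fold and 2.66-fold higher (adjusted p = 0.0083 and 0.0152). Pik3c2g and Ccdc151, each well above background on 1 vehicle array, were at 2.49 ± 0.60 and 2.10 ± 0.17. Inafm2 at 1.43 ± 0.13, Olfr213 at 1.41 ± 0.20, Spata31d1a at 1.36 ± 0.17, Fam186b at 1.33 ± 0.28, the activin antagonist gene Fst at 1.33 ± 0.25, the histone gene H4f16 at 1.31 ± 0.15 and the vomeronasal receptor gene V1ra8 complete the set of 12. The other Pik3c2g probe was at -1.15, and the deposited value table gave -0.72 for the gene.

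The largest decreases were also of genes near background in the VND3207 mice. Syt10, a synaptotagmin gene, was at least 73.1-fold lower (adjusted p = 0.0431), but its SD between vehicle mice was 3.29 on the log2 scale. The bound was 36.0-fold, 39.8-fold and 272-fold without vehicle replicates 1, 2 and 3, and the call was lost without any 1 array other than vehicle replicate 3, with an adjusted p of up to 0.138. Olfr622 (at least 10.2-fold), Cecr2 (8.74-fold), Olfr312 (8.67-fold), Cldn34c4 (8.58-fold), Krtap19-2 (8.55-fold), Olfr1431 (7.39-fold), Hyal6 (7.05-fold) and Cpa1 (6.86-fold) were also without a VND3207 array well above background, with the fold as a lower bound. For Olfr312 the bound was 7.19-fold, 6.72-fold and 13.5-fold without VND3207 replicates 1, 2 and 3. The sizes of these decreases depended on the correction, after which the bounds were 5.26-fold for Olfr622, 5.66-fold for Cecr2, 4.67-fold for Olfr312, 5.68-fold for Cldn34c4, 4.80-fold for Krtap19-2, 5.31-fold for Olfr1431 and 8.62-fold for Hyal6. Dlx6, a homeobox gene well above background on 1 VND3207 array, was at -4.10 ± 0.31, Prss58 at -3.41 ± 0.20 and Olfr843 at -3.37 ± 0.57, or -3.25, -2.96 and -2.67 after the correction. After the correction 11 of the 12 increases and 10 of the 12 decreases remained past the threshold. Those lost were Mas1, at least 1.92-fold higher (adjusted p = 0.134), Syt10, at least 42.8-fold lower (adjusted p = 0.0811), and Cpa1, at least 3.67-fold lower (adjusted p = 0.134).

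The same rule applied to genes brighter than the 75th percentile, a choice made after the values were seen, named other genes. Lower with VND3207 were Wdr45b at -1.98 ± 0.21, Haao, an enzyme gene of the kynurenine pathway, at -1.82 ± 0.25, and Pinx1, a telomerase inhibitor gene, at -1.69 ± 0.24. Next came Defa-rs12, a defensin-related gene of Paneth cells, at -1.56 ± 0.25, Stfa2 at -1.54 ± 0.27, Arl4c at -1.40 ± 0.13 and Myo18b at -1.38 ± 0.17. The rest were Erp27 at -1.36 ± 0.12, Akap7 at -1.33 ± 0.24, Mettl7a2 at -1.31 ± 0.20, Nmur2, the neuromedin U receptor gene of the gut and nervous system, at -1.30 ± 0.15 and Tmem161a at -1.29 ± 0.12. All 12 remained past the threshold after the correction. Higher, beside Inafm2, H4f16 and Ly6a, were Hap1 at 1.05 ± 0.15, Trim43c at 1.00 ± 0.12, Psme3 at 0.79 ± 0.20, and Scgb3a1 at 0.76 ± 0.17. They were followed by Eif4ebp3, a translation repressor gene, at 0.74 ± 0.14, the metallothionein gene Mt3 at 0.69 ± 0.16, the histone gene H4c11 at 0.69 ± 0.17, Impg1 at 0.68 ± 0.13 and Kdm2a at 0.66 ± 0.12. Of these 12 increases 9 remained after the correction, and Psme3 was at 0.49 (adjusted p = 0.19), Scgb3a1 at 0.64 (adjusted p = 0.0677) and Impg1 at 0.53 (adjusted p = 0.0613). At least 1 other probe of Akap7, Myo18b and Kdm2a had the opposite sign, and other probes of Wdr45b and Tmem161a were at -0.09 and -0.12.

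Genes called lower were spread unevenly over the array. With the array rows divided into 4 equal bands, 16.9% of the named genes with a probe in the last band were called lower, against 5.23% in the first band. Among genes dimmer than the 75th percentile the share went from 7.7% to 29.3%, and among brighter genes from 2.89% to 3.05%. With the genes divided into 4 equal groups by probe GC content, 13.3% were called lower in the group with the highest GC content, against 4.03% in that with the lowest. On corrected values 7.01% were still called lower in the last band of rows against 3.09% in the first, and 5.80% against 2.75% called higher.

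**Figure D4:**
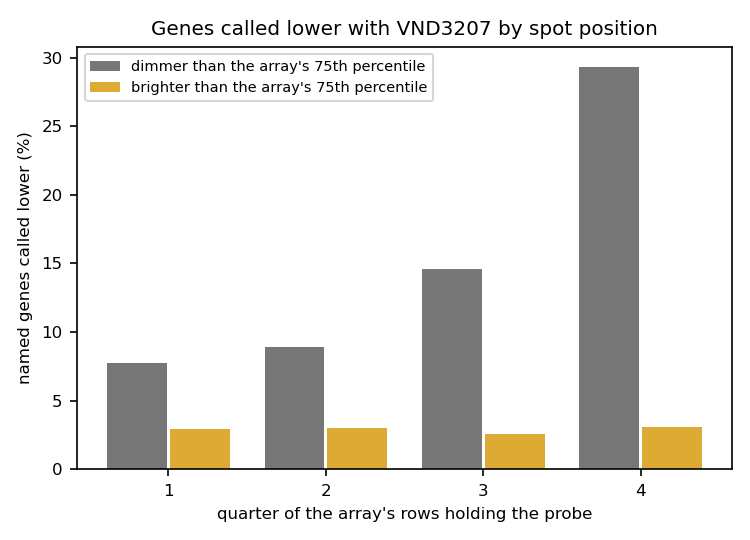
Percent of named genes called lower with VND3207, by which of 4 equal bands of array rows holds the probe, for genes dimmer (grey bars) and brighter (yellow bars) than the 75th percentile of the arrays. The grey bars go from 7.7% to 29.3% and the yellow bars from 2.89% to 3.05%.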

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

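The tests of spot position, of probe GC content and of what remained after correction were all chosen after the counts of genes had been seen.

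The median signal of the local background, which no comparison of the report used, averaged 30.7 on the VND3207 arrays and 23.7 on the vehicle arrays, with an SD of 0.577 in each group and no overlap. Of 10 control transcripts of the kind spiked into samples, 1 dim transcript was lower on the VND3207 arrays by a log2 difference of -1.16, with the groups apart by more than 3 times their SD. The other 3 of the 4 dimmest were at 0.43, -0.15 and 0.38 and the 2 brightest at -0.40 and -0.32, so the control transcripts did not move in 1 direction. The share of named genes called lower was 16.9% in the last of 4 equal bands of array rows, against 5.23% in the first, although a gene's place on the array has no biological meaning.

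Many more genes were lower than higher with VND3207, 1616 against 143. Spot position was tested by the ratio of the shares called lower in the last and first bands of rows, which was 3.23 against 0.875 to 1.35 in 1000 permutations among genes of like brightness, and probe GC content by the ratio between the highest and lowest of 4 GC groups, 3.29 against 0.962 to 1.42. Both ratios are consistent with a technical contribution to the lower calls, mainly among dim genes, where the share went from 7.7% to 29.3% by rows and from 5.80% to 22.4% by GC content, against 2.89% to 3.05% and 2.46% to 3.30% among brighter genes. After correction for both and for brightness, 752 genes were lower and 634 higher, of which 78 had been higher at first. The corrected calls still followed the rows. Between the first and last bands the share called lower went from 3.09% to 7.01%, and that called higher from 2.75% to 5.80%. The correction takes smooth trends out of each array, which draws the counts towards balance whether or not a trend is technical. The balance therefore cannot show the cause. Among brighter genes 114 were higher and 322 lower on corrected values, against 46 and 230 before. Of the 1616 genes lower at first, 656 stayed past the threshold. Whether those 656 come from VND3207 or from the slide cannot be told apart, because each slide and scan held 1 group.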

How the results depend on the processing

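The tests of brighter genes only and of values corrected for spot position, brightness and GC content were chosen after the results were seen, and the others before the data were examined. Slide and scan could not be run as a block, because each held 1 group. Dim genes limit the counts: signal was well above background for 58.8% to 70.0% of spots.

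Counts of genes were 371 higher and 986 lower with quantile normalization, 422 and 987 with normexp and quantile normalization, 366 and 965 in the deposited value table, 221 higher without a filter on dim probes, 964 lower with well above background signal required on all 6 arrays, 237 higher with the trend and robust variance model and 221 higher with array weights. Brighter genes only gave 46 and 230, corrected values 634 and 752, and brighter genes on corrected values 114 and 322. An adjusted p under 0.10 gave 395 higher, an unadjusted p with 2-fold 35 and 1034, and an adjusted p with 1.5-fold 78 higher. Leaving out each array gave 47 to 131 genes higher and 900 to 1519 lower. Without vehicle replicates 1, 2 and 3 there were 91, 55 and 67 higher, and without VND3207 replicates 1 and 2 there were 47 and 63. Fewer genes or arrays lower the counts by construction for the stricter filter, the brighter genes and the arrays left out. For the other settings the cause was not tested.

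The number of lists higher was 1 with quantile normalization, with normexp and quantile normalization, in the deposited value table, without the filter, on corrected values and on brighter genes with corrected values, and it was cholesterol synthesis each time. It was 0 with an estimated correlation or with fry, 5 (and 2 lower) with signal on all 6 arrays, 3 (and 4 lower) for brighter genes only, with 2 lower in the trend and robust model. Leaving out each array gave 5 to 11 lists higher and 0 to 2 lower. Cholesterol synthesis was past the threshold in 18 of 20 alternatives (adjusted p from 4.07e-09 to 0.822), p53 targets and epithelial regeneration in 12, mitosis in 10, interferon response in 8, DNA replication and end joining in 7 and T and NK cells in 5.

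The replicate block, with the replicate number as a block, gave 59 genes higher and 1038 lower. The labels do not say whether the same number pairs mice. Deviations from the group means correlated across genes at an r of 0.117, -0.110 and -0.0433 for mice of the same number. For mice of unlike number r was -0.242 to 0.295, so these values give no sign of pairing but cannot exclude it.

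On brighter genes with corrected values the medians of mitosis and end joining were -0.038 and -0.049. With each array left out the interferon median went from -0.21 (without vehicle replicate 3) to 0.47, and that of smooth muscle from -1.01 to 0.13 (without VND3207 replicate 3). With quantile normalization, with normexp and in the value table, Itln1 was at 0.013, 0.016 and 0.0021, Lct at 0.045, 0.080 and 0.042, and Reg3b at 0.0088, 0.033 and 0.00016, and Pik3c2g was at -0.72 in the value table. On corrected values Pou2f3 was at 0.091, Fcer2a at 0.16 and Col15a1 at 0.26, and with the mean of its probes Kdr was at 0.0027. The cause was not tested. Of 91 named genes past the threshold 30 kept their call under every alternative that could be run on them, and of 8 lists 0 did.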

Other observations

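The tests weighed here for cholesterol synthesis and smooth muscle were chosen after the results were seen, and the comparison of splits of the arrays before.

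Single mice differed in several tissue programmes irrespective of their group. Interferon response genes had the lowest score in vehicle replicate 3, at -0.93, and the highest in vehicle replicate 2, at 0.58, with the VND3207 mice between -0.12 and 0.18. MHC class II genes were also lowest in vehicle replicate 3, at -0.46, and highest in VND3207 replicate 1, at 0.28. Adipose genes were highest in VND3207 replicate 1, at 2.81, and lowest in VND3207 replicate 3, at -1.99, with a vehicle mouse at -1.71. Of the 38 lists, 8 had scores that did not overlap between the groups, among them pancreatic acinar cells, with -0.50 to -0.27 in the VND3207 mice and 0.09 to 0.69 in the vehicle mice. Among single named genes the groups did not overlap for 28.8%, where chance gives 10%.

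Cholesterol synthesis genes were higher with VND3207 by a median of 0.31, with 18 of 20 members above 0. The smooth trends fitted to spot position, brightness and probe GC content did not account for that median, which was still 0.28 on values corrected for them. Position as a source cannot be excluded, because 7.01% of named genes were still called lower in the last band of rows, against 3.09% in the first. On the corrected values none of 10000 lists matched on brightness and GC content reached the list's median, which gives 1e-04, the smallest value such a draw can give. The matched genes were drawn independently and not matched on position. The 1e-04 thus does not allow for genes that vary together, and the estimated correlation of this list was 0.426. Differences between mice that the list's genes share, whatever the group, stay open, since another split of the 6 arrays gave a median of size 0.293 and 4 of the 9 other splits passed camera. Leaving out VND3207 replicate 3, tested first as a possible source, left the median at 0.24. An effect of VND3207 may be present, but it and the slide cannot be told apart, because each slide held 1 group.

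Smooth muscle genes were lower with VND3207 by a median of -0.64 without passing the test. An effect alike in the 3 mice is argued against, because 1 VND3207 array scored below every vehicle array and the other VND3207 arrays, at 0.41 and 0.33, did not. A smaller share of the muscle wall in the piece of jejunum from VND3207 replicate 3 is a candidate explanation. Without that mouse the list median was 0.125, and enteric neuron and glia genes, from the same layer, were lowest in it too. No record of the dissection is in the files, so this stays a hypothesis.

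The 6 arrays can be divided into 3 and 3 in 10 ways, too few for a share under 5%. The real split gave 143 genes higher and 1616 lower and the highest of the other splits 0 and 0 (limma), so that 1 split, the real one, reached each count. At an unadjusted p under 0.05 the real split gave 3425 genes and the others 122 to 1344. Each other split mixes the slides, so a difference between slides or treatments widens the spread within its groups and lowers its counts. The 0 and 0 are therefore no measure of chance alone. For lists, 6 of the 10 splits had as many in a direction as the 8 higher, with up to 11 in another split. Lists called by camera at a preset correlation thus also arise in splits that mix the treated and vehicle mice.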
